A study of Homo sapiens with 4 samples.

How the data were processed

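RNA from AGO2 immunoprecipitates of MCF10A cells was measured in 4 libraries, 2 with the empty vector and 2 with pre-miR-203a, and groups and replicate numbers were taken from the titles in the labels. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made by an Illumina mRNA protocol. The submitters' processing notes name FastQC 0.11.5, MultiQC 1.6, featureCounts 2.0.0, DESeq2 1.28.1 and the genome build hg38. The aligner, the annotation release and the strand setting are not given in the sources used here.

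One deposited table gives FPKM per feature and library, per the file headers. The other gives, per the file headers, TPM per library and the authors' comparison of the groups. In it the deposited baseMean is a signal averaged over the 4 libraries of counts divided by size factors, per the file headers. The authors' log2 fold changes and their standard errors are coded as the empty vector over pre-miR-203a, since all 2926 features with an absolute log2 change over 1 have that sign, and their sign was turned for the text. The authors' p-values and adjusted p-values are DESeq2's, per the file headers and the submitters' processing notes, and 15433 features have an adjusted one. The tables list 17857 features, of which 17611 have Ensembl identifiers and 246 are repeat families, and the lowest deposited baseMean is 2.03. Of the Ensembl identifiers, 17526 matched the table of gene names used. MIR203A was placed with RefSeq coordinates on GRCh38.p14, the assembly also called hg38.

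The design named a count-based test for raw counts and limma for FPKM. The deposited tables hold FPKM and no count columns, so limma was used. Whole reads were recovered from the steps of the deposited FPKM values of low features together with the deposited baseMean. Of 71428 values, 100% came out within 0.01 of a whole read, and feature lengths came out whole for 100% of features. The recovered reads gave 26900946, 24584075, 31645016 and 42765468 reads for empty vector replicates 1 and 2 and pre-miR-203a replicates 1 and 2, and were otherwise used for read floors and for an added alternative. A floor of 3 reads per library was used where both empty vector libraries had 0 reads. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

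Features with at least 1 FPKM in at least 2 libraries were tested, 10879 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 0.5) with the group as the only term and eBayes with trend and robust options, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale and understate the change of low features. With 2 libraries against 2, an exact permutation test cannot give a p below 0.33, so no single-value test was made. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, over the 24 of 27 lists with at least 5 tested members. The lists, like the test and its thresholds, were written down before the data were examined, the reported miR-203 targets from general knowledge of the field. Of the 10 lists that passed camera, 0 did with an estimated correlation, and fry passed the microRNA host, histone and luminal lists (adjusted p = 0.0172, 0.0172 and 0.0336), but not the host list without MIR203A and MIR203B (0.0523). With any library left out, on TPM and with voom, 0 lists passed fry. fry asks whether a list's genes move one way on balance and does not compare them with other genes.

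The genes named were set by a rule fixed before the data were examined: among features past the threshold with at least 1 FPKM on average whose groups did not overlap, the 12 with the largest change each way, and if fewer than 5 passed, the 6 with the smallest p in that direction. From each list up to 4 members past the threshold were named, or, if none passed, the 2 with the smallest p. MIR203A, AGO2, TP63, SNAI2, BMI1, ABL1 and SOCS3 were always given. Other genes named, and those from the authors' deposited table, were chosen after their values were seen.

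The fit was tested on simulated data made for this comparison from 10782 features, with changes added to 200 of them. It recovered 91 of 100 features changed 16-fold and 34 of 100 changed 4-fold, with 10 false calls among 10582 unchanged features, and it called 1 of 20 unchanged lists. The simulated genes varied independently and the replicate number had no effect. In the data, the estimated correlation was 0.15 within the G1/S list and 0.26 within the G2/M list. Deviations of same-numbered libraries correlated at 0.67. The simulation therefore does not give camera's rate of false calls for lists of correlated genes.

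Alternatives were a replicate block, each library left out, pseudocounts of 0.1 and 1, no filter, TPM, TMM-scaled FPKM, and a minimum log2 change of 1. Added after seeing the data were limma's voom on the recovered reads (TMM scaling, at least 10 reads in 2 libraries), the same with the replicate block, FPKM without mitochondrial features, and the host list without MIR203A and MIR203B. A test of miR-203a seed matches in 3-prime UTRs was planned and needs a genome and annotation, which were not used here. Random lists were drawn 10000 times within 20 bins of mean expression. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.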

Results

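RNA bound to AGO2, the Argonaute protein that carries microRNAs to their target transcripts, was sequenced from MCF10A cells, an immortalized line of human mammary epithelium. The cells had been transduced with a retrovirus carrying the miR-203a precursor (pre-miR-203a) or with the empty vector, and were kept under puromycin. Each group had 2 libraries of RNA from AGO2 immunoprecipitates, and the comparison asks which transcripts are found with AGO2 once miR-203a is added. The empty vector libraries held 26900946 and 24584075 counted reads and the pre-miR-203a libraries 31645016 and 42765468. Input RNA was not analysed here, so a higher value can come from more of an RNA in the cells or from more of it bound to AGO2. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

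MIR203A, the hairpin that the vector carries, rose from 5.86 ± 1.12 FPKM (SD, n = 2) in the empty vector libraries to 14334 ± 5316 FPKM (SD, n = 2) in the pre-miR-203a libraries. With it rose reads on MIR222, MIR27B and MIR103A2, hairpins of other microRNAs. Reads on MIRLET7BHG and MIR22HG, the host transcripts of let-7b and miR-22, rose too. The 2 protein-coding transcripts that rose were SULT1E1, an estrogen sulfotransferase, and ID2, an inhibitor of basic helix-loop-helix transcription factors. These were 8 of 10879 tested features, and 0 fell in limma at an adjusted p under 0.05. At an unadjusted p under 0.05 limma gave 463 higher and 707 lower features. limma's voom on the recovered reads gave 11 higher and 1 lower at an adjusted p under 0.05, and 920 and 763 at an unadjusted p under 0.05. The count of 0 lower features depends on leaving the replicate number out of the fit. With a replicate block, limma gave 465 higher and 1009 lower at an adjusted p under 0.05. The labels do not establish such pairs. Across tested features, log2 values correlated at 0.955 between the empty vector libraries and at 0.908 between the pre-miR-203a libraries. Same-numbered libraries of the 2 groups correlated at 0.916 (replicate 1) and 0.936 (replicate 2). Pre-miR-203a replicates 1 and 2 correlated at 0.896 and 0.871 with the other-numbered empty vector library. The replicate number thus went with differences that the main fit leaves out.

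The MIR203A hairpin (ENSG00000207568.1) lies on chromosome 14, from 104117405 to 104117514 of GRCh38.p14. It held 15 and 18 reads in the empty vector libraries and 36810 and 85114 reads in the pre-miR-203a libraries, a log2 change of 11.10 ± 0.52 (SE) with a limma adjusted p of 0.00136. Reads from the vector and from the cells' own gene cannot be separated in these values. MIR203B, an overlapping hairpin on the opposite strand, had 0 reads in both empty vector libraries and 4 and 21 in the pre-miR-203a libraries. Whether reads were counted by strand is not given in the sources used here, so they could have come from MIR203A transcripts.

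MIR222 and MIR27B had 0 reads in both empty vector libraries. Against a floor of 3 reads per library, MIR222 was at least 33.6-fold higher and MIR27B at least 9.24-fold higher, and these bounds cover counting error only. MIR222 stood at 53.4 and 17.9 FPKM and MIR27B at 5.86 and 16.4 FPKM in the pre-miR-203a libraries. MIRLET7BHG went from 0.32 ± 0.181 to 11.9 ± 1.62 FPKM (SD, n = 2), a log2 change of 3.93 ± 0.29 (SE). MIR22HG went from 4.35 ± 0.378 to 51.5 FPKM, where the pre-miR-203a libraries were at 51.5 and 51.4, a log2 change of 3.42 ± 0.31 (SE). SULT1E1 went from 0.134 ± 0.114 to 5.04 ± 0.138 FPKM, MIR103A2 from 0.998 ± 0.0635 to 9.35 ± 1.19, and ID2 from 0.284 ± 0.0925 to 3.58 ± 0.405 (SD, n = 2). The limma adjusted p-values of these 7 features lay between 0.0164 for MIRLET7BHG and 0.0491 for ID2. MIR222, MIR27B, MIRLET7BHG, SULT1E1 and ID2 were under 1 FPKM in both empty vector libraries. The filter admitted them only where both pre-miR-203a libraries were higher, so it fixed their order. MIR222 lies within the host gene MIR222HG and other hairpins within their own hosts, so a hairpin and its host can share reads. A hairpin and its host are therefore not separate evidence. The libraries were made by an mRNA protocol, and whether mature microRNAs changed was not examined.

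Without a filter on low values, or on TPM, MIR203A alone passed and the other 7 features did not. MIR27B and ID2 did not pass with a pseudocount of 1, nor MIR27B and MIR103A2 with limma's voom. The count also moved when a single library was left out: 44 higher and 9 lower without empty vector replicate 1, 69 and 38 without empty vector replicate 2, 227 and 531 without pre-miR-203a replicate 1, and 478 and 204 without pre-miR-203a replicate 2.

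**Figure D1:**
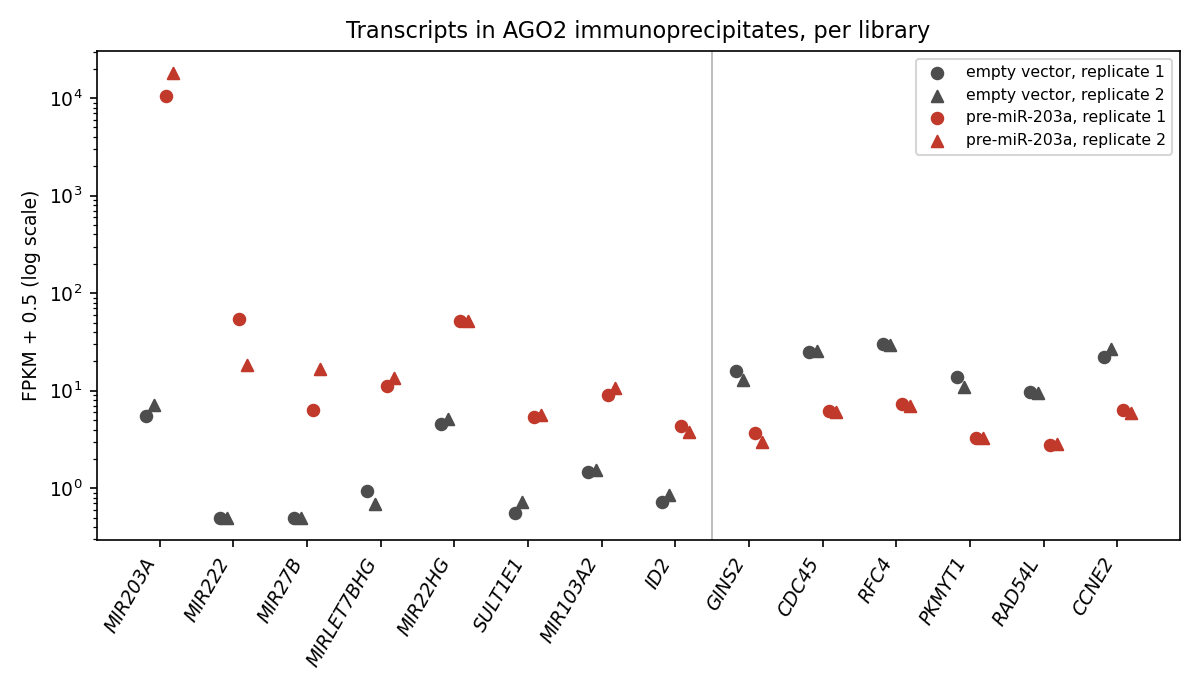
FPKM plus 0.5 (log axis) of the 8 transcripts that passed the test upward, left of the line, and of the 6 with the smallest p downward, right of the line, with 1 point for each of the 4 libraries. The upward transcripts were chosen among those whose groups did not overlap, and MIR203A reaches 10575 and 18093 FPKM. For MIR222, MIR27B, MIRLET7BHG, SULT1E1 and ID2, under 1 FPKM in both empty vector libraries, the filter fixed that order.

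Host transcripts of microRNAs rose as a group. The list fixed for them had 13 tested members, with a median log2 change of 2.18, or 1.82 with MIR203B set at its lower bound. Of the 13 members, 8 were under 1 FPKM in both empty vector libraries, so the filter admitted them only where both pre-miR-203a libraries were higher. The other 5 were also higher in both, as were 14 of all 15 listed members without a filter, where the median was 1.82 (limma's camera, adjusted p = 3.45e-20, and adjusted p = 0.303 with an estimated correlation). With the filter, the set test passed (limma's camera, adjusted p = 1.87e-25), and the call was lost with adjusted p = 0.183 with an estimated correlation. Of the tested members, 3 rose over all features (MIR203A, MIRLET7BHG and MIR22HG) and 13 adjusted over the list alone. Without MIR203A and MIR203B, an alternative chosen after seeing the data, the remaining 11 members had a median of 1.82 and camera's adjusted p was 7.51e-21 (adjusted p = 0.215 with an estimated correlation). limma's fry passed the full list (adjusted p = 0.0172) but not these 11 members (adjusted p = 0.0523), and its call on the full list ended with any library left out (adjusted p = 0.3 and 0.211 without empty vector replicates 1 and 2, 0.305 and 0.245 without pre-miR-203a replicates 1 and 2), on TPM (0.103) and with voom (0.073). MIR205HG, host of miR-205, went from 18.2 and 11.7 to 136.9 and 96.2 FPKM, and MIR222HG from 2.3 and 1.2 to 31.5 and 13.9 FPKM. Both were named after their values were seen, and neither passed over all features (limma adjusted p = 0.101 for each).

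Transcripts of DNA replication and mitosis fell as groups. The G1/S list had a median log2 change of -1.31 over 30 tested members (limma's camera, adjusted p = 3.36e-21) and the G2/M list -1.22 over 33 (adjusted p = 5.65e-18). Both calls were lost with an estimated correlation (adjusted p = 0.215 for G1/S and adjusted p = 0.277 for G2/M with an estimated correlation). limma's fry passed neither list (adjusted p = 0.0828 for G1/S and 0.113 for G2/M). Over all features 0 members of either list passed in limma, while adjusted over the list alone 22 of the 30 G1/S members and 24 of the 33 G2/M members were lower. Both pre-miR-203a libraries lay below both empty vector libraries for 27 of the G1/S and 30 of the G2/M members. Over all tested features 2792 of 10879 lay in that order, and 41% lay in one order or the other. Chance would give 33.3% for either order if all 4 libraries varied alike and independently. Deviations of same-numbered libraries correlated at 0.67, so that rate does not hold here. GINS2 and CDC45, parts of the replicative helicase, stood at 14 ± 2.28 and 24.7 ± 0.224 FPKM with the empty vector and at 2.87 ± 0.50 and 5.67 ± 0.114 FPKM with pre-miR-203a (SD, n = 2). CCNE2, which encodes cyclin E2, stood at 24.1 ± 3.07 and 5.6 ± 0.35 FPKM. RFC4, a subunit of the clamp loader, had a log2 change of -2.05 ± 0.31 (SE), PKMYT1, a kinase that inhibits CDK1, -1.91 ± 0.29, and the recombination factor RAD54L -1.78 ± 0.27. For these 6 transcripts, the smallest p-values downward, limma's adjusted p was 0.102. Of the G2/M list, the centromeric histone CENPA had a log2 change of -1.39 ± 0.27 (SE) and the mitotic kinase PLK1 -1.87 ± 0.37, with limma adjusted p-values of 0.154 and 0.162.

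In the replication-dependent histone list, the few genes tested moved the other way. Only 5 of its 44 genes were tested, with a median log2 change of 1.04, and the set rose (limma's camera, adjusted p = 1.38e-05, and adjusted p = 0.215 with an estimated correlation). Over all features 0 members passed and 3 were higher adjusted over the list alone. H2BC12 went from 0.824 to 2.49 FPKM and H2AC6 from 1.47 to 5.85 FPKM (means, n = 2). H2BC12 held 11 and 10 reads in the empty vector libraries and 41 and 50 in the pre-miR-203a libraries. The libraries were made by an mRNA protocol, and how well it captures histone transcripts was not examined. The values therefore do not speak for the list's untested genes. H2BC12 and H2BC5 passed the 1 FPKM filter only through the pre-miR-203a libraries. Without a filter the median over 14 histone genes was 0.25, with the set still past camera (adjusted p = 8.91e-04, and adjusted p = 0.303 with an estimated correlation).

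Epithelial transcripts of luminal and stratified cells rose as sets in limma's camera. Of these lists limma's fry passed only the luminal one (adjusted p = 0.0336), not keratinocyte differentiation (0.113) or epithelial junctions (0.2). Of the luminal mammary list 13 of 24 genes were tested, with a median log2 change of 0.89 (limma's camera, adjusted p = 4.35e-07, and adjusted p = 0.215 with an estimated correlation). The list's median in each library, relative to the mean of the empty vector libraries, was 0.92 and 0.80 with pre-miR-203a and -0.05 and 0.05 with the empty vector. In 8 of the 13 members both pre-miR-203a libraries were higher. The groups overlapped for FOXA1 (0.39), EPCAM (0.23), KRT18 (0.19), ESR1 (0.16) and XBP1 (-0.03). Over all features 0 luminal members passed, and 6 were higher adjusted over the list alone. Of these, ELF3, an epithelial transcription factor, stood at 3.52 ± 0.17 FPKM with the empty vector and 11.8 ± 0.656 with pre-miR-203a, and the mucin MUC1 at 3.38 ± 2.78 and 23.2 ± 1.18 (SD, n = 2). Of the keratinocyte differentiation list 14 of 35 genes were tested, with a median of 1.06 (limma's camera, adjusted p = 2.31e-07, and adjusted p = 0.215 with an estimated correlation). Over all features 0 of these members passed, and 8 were higher adjusted over the list alone. SPRR1A, a cornified envelope precursor, had a log2 change of 1.58 ± 0.29 (SE), and the plakin PPL 2.32 ± 0.45. KRT13 and KRT16, named after their values were seen, passed the filter only through the pre-miR-203a libraries. Without a filter, limma's camera still passed, with smaller medians: 0.39 over 17 luminal members (adjusted p = 2.33e-06) and 0.34 over 23 keratinocyte members (adjusted p = 1.09e-05). Both calls were lost in camera with an estimated correlation (adjusted p = 0.303 for each). The epithelial junction list had a median of 0.48 over 26 members (limma's camera, adjusted p = 2.46e-06, and adjusted p = 0.277 with an estimated correlation), with 0 members past the test over all features and 1, OVOL1, higher adjusted over the list alone. OVOL1, a repressor of mesenchymal genes that passed the filter only through the pre-miR-203a libraries, had a log2 change of 2.11 ± 0.35 (SE), and the tight junction protein CLDN1 1.86 ± 0.45. The junction median was 0.23 without pre-miR-203a replicate 2 and 0.74 without pre-miR-203a replicate 1.

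The basal mammary list had a median log2 change of 0.30 over 24 members and passed the set test (limma's camera, adjusted p = 0.0339, and adjusted p = 0.579 with an estimated correlation), with 0 members past the test over all features and 0 adjusted over the list alone. This call ended without empty vector replicate 1 (adjusted p = 0.409), without pre-miR-203a replicate 2 (0.574), without a filter on low values (0.091), on TPM (0.0612) and with limma's voom (0.101). VIM, which encodes vimentin, stood at 17.1 ± 1.43 FPKM with the empty vector and 8.21 ± 3.02 with pre-miR-203a (SD, n = 2), a log2 change of -1.06 ± 0.36 (SE) and a limma adjusted p of 0.348. The mesenchymal list had a median of 0.03 over 24 members and did not pass (limma's camera, adjusted p = 0.366), and 0 of its members passed over all features or adjusted over the list alone. SNAI2 had the smallest p in both the basal and the mesenchymal list, with a log2 change of 2.24 ± 0.70 (SE). FOXC2, a forkhead transcription factor of the mesenchymal list, had a log2 change of 0.81 ± 0.27 (SE).

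**Figure D2:**
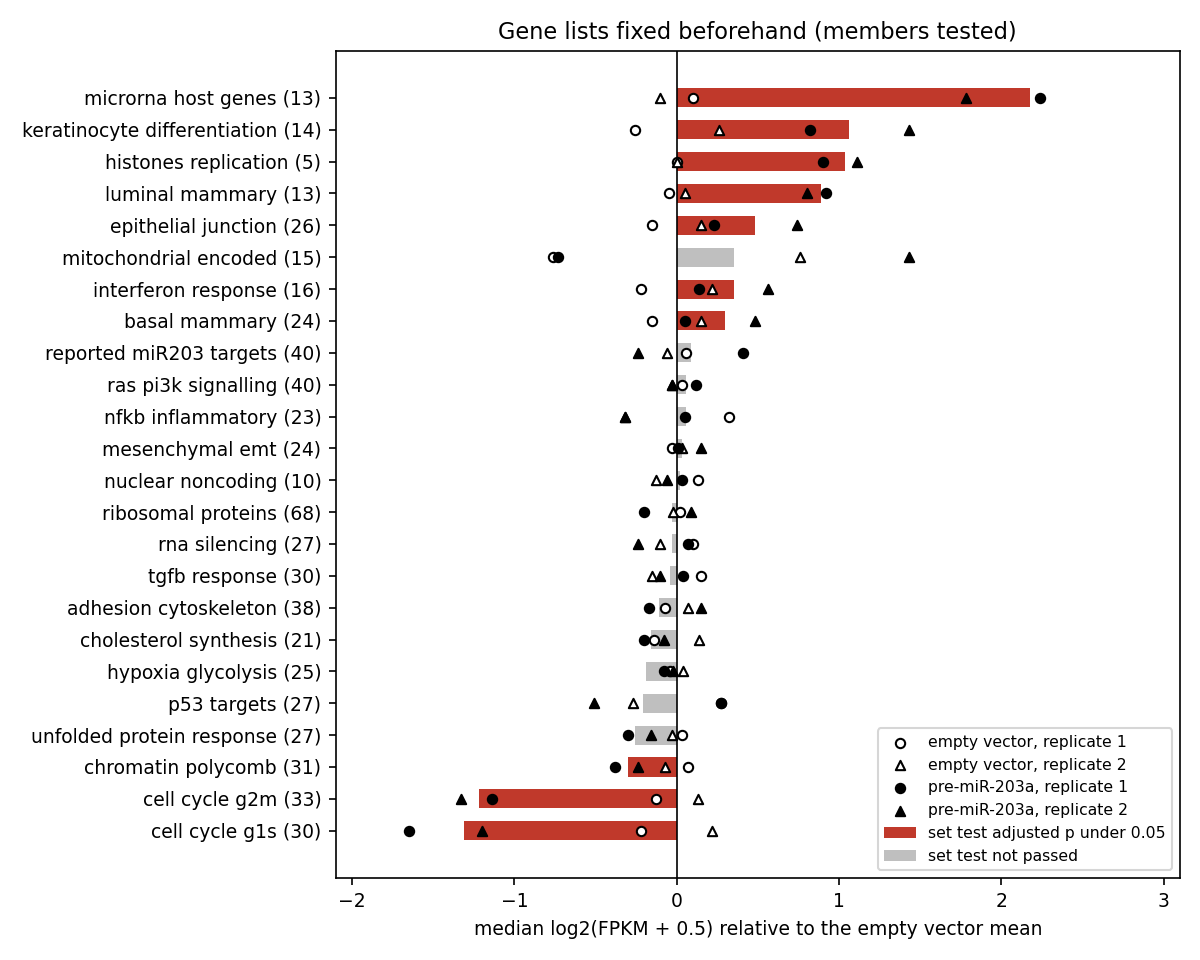
Median log2(FPKM + 0.5) of each gene list with at least 5 tested members, relative to the mean of the empty vector libraries. Bars give the median fitted log2 change, red where limma's camera passed at an adjusted p under 0.05, and points give the list's median in each of the 4 libraries. The microRNA host list stands at 2.18 and the G1/S list at -1.31, while the reported miR-203 targets are at 0.41 and -0.24 in the pre-miR-203a libraries.

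Transcripts reported as direct miR-203 targets did not move as a set. The list's 40 tested members had a median log2 change of 0.09 (limma's camera, adjusted p = 0.263, and adjusted p = 0.962 with an estimated correlation). Relative to the mean of the empty vector libraries, the list's median was 0.41 in pre-miR-203a replicate 1 and -0.24 in pre-miR-203a replicate 2, against 0.06 and -0.06 in the empty vector libraries. Over all features 0 members passed in limma, and adjusted over the list alone 1 was higher and 1 was lower. The higher was DKK1, a secreted Wnt inhibitor, at 15.8 ± 4.26 FPKM with the empty vector and 68.4 ± 17 with pre-miR-203a, and the lower was SKP2, an F-box protein of the cell cycle, at 72.5 ± 9.96 and 16.8 ± 6.91 (SD, n = 2). The set test passed upward without empty vector replicate 1 (median 0.19, limma's camera adjusted p = 0.0381) and without pre-miR-203a replicate 2 (0.41, adjusted p = 3.99e-05), and these calls were lost with adjusted p = 0.902 and 0.577 with an estimated correlation. The median turned negative without pre-miR-203a replicate 1 (-0.24). On TPM it was -0.01, where all tested features had a median of -0.15 and camera's direction stayed upward.

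SNAI2, which encodes the transcription factor SLUG, stood at 61.5 and 43.0 FPKM in the empty vector libraries and at 503.9 and 118.3 FPKM in the pre-miR-203a libraries, a log2 change of 2.24 ± 0.70 (SE) with a limma adjusted p of 0.319. TP63, the p63 transcription factor of basal epithelium, stood at 8.51 and 10.2 FPKM and at 32.0 and 12.2 FPKM (log2 change 1.05 ± 0.48, limma adjusted p = 0.502). The kinase ABL1 had a log2 change of 0.45 ± 0.33 (SE), the Polycomb protein BMI1 -0.30 ± 0.32, and the cytokine signalling inhibitor SOCS3 -0.13 ± 0.40. SNAI2, TP63, ABL1, BMI1 and SOCS3 are all on the list of reported miR-203 targets. The sign for SOCS3 turned without empty vector replicate 1 (0.17) and without pre-miR-203a replicate 2 (0.31).

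The transcript of AGO2 itself stood at 16.7 ± 5.25 FPKM with the empty vector and 18.0 ± 7.9 with pre-miR-203a (SD, n = 2), a log2 change of 0.07 ± 0.43 (SE) with a limma adjusted p of 0.976. Its sign turned without empty vector replicate 2 (-0.25), without pre-miR-203a replicate 1 (-0.38) and on TPM (-0.02). On TPM all tested features had a median of -0.15. The list of microRNA silencing factors had a median of -0.03 over 27 members (limma's camera, adjusted p = 0.888), with 0 members past the test over all features and 0 adjusted over the list alone. TARBP2, a partner of Dicer, had a log2 change of -1.18 ± 0.36 (SE), and the helicase MOV10 -0.84 ± 0.40.

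The Polycomb and chromatin list fell slightly, with a median of -0.30 over 31 members (limma's camera, adjusted p = 0.0281, and adjusted p = 0.301 with an estimated correlation), 0 members past the test over all features and 1 lower adjusted over the list alone. That member was CBX2, at -1.44 ± 0.28 (SE), and the methyltransferase EZH2 was at -1.22 ± 0.30. The call ended without empty vector replicate 1 (adjusted p = 0.0519), without empty vector replicate 2 (0.0791), without pre-miR-203a replicate 1 (0.215), without a filter (0.0502), on TPM (0.0675) and with limma's voom (0.0532). The interferon list rose with a median of 0.35 over 16 members (limma's camera, adjusted p = 0.00877, and adjusted p = 0.579 with an estimated correlation), with 0 members past the test over all features and 0 adjusted over the list alone. Without a filter the median was 0.21 over 32 members. Its call ended without empty vector replicate 1 (0.125) and without pre-miR-203a replicate 2 (0.12). OAS1, which senses double-stranded RNA, stood at 0.519 FPKM in both empty vector libraries and at 5.04 and 1.83 FPKM with pre-miR-203a, and SAMD9 had a log2 change of 1.13 ± 0.35 (SE).

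The other 11 tested lists did not pass limma's camera. Their median log2 changes were -0.21 for p53 targets (27 members), 0.06 for NF-kB and inflammation (23), -0.04 for the TGF-beta response (30), 0.06 for RAS and PI3K signalling (40), -0.11 for adhesion and cytoskeleton (38), -0.16 for cholesterol synthesis (21), -0.26 for the unfolded protein response (27) and -0.19 for hypoxia and glycolysis (25). Ribosomal proteins were at -0.03 (68 members), nuclear non-coding RNAs at 0.02 (10) and mitochondrially encoded transcripts at 0.35 (15). Among these lists, ID2 of the TGF-beta response rose over all features and also adjusted over the list alone, and no other member passed either way. The p53 list passed without pre-miR-203a replicate 1 (-0.51, adjusted p = 0.0119), the inflammation list without empty vector replicate 1 (0.14, adjusted p = 0.0247) and the mitochondrial list without pre-miR-203a replicate 1 (1.43, adjusted p = 0.019). These calls were lost with adjusted p = 0.796, 0.787 and 0.677 with an estimated correlation. The medians turned without empty vector replicate 1 for p53 (0.13) and mitochondrial transcripts (-0.36), without pre-miR-203a replicate 2 for the same lists (0.27 and -0.73), and for inflammation without empty vector replicate 2 (-0.27) and without pre-miR-203a replicate 1 (-0.32). Without pre-miR-203a replicate 1, RAS and PI3K signalling (-0.03), adhesion (0.15), ribosomal proteins (0.09) and nuclear non-coding RNAs (-0.06) also turned. Without empty vector replicate 2, adhesion (0.05), cholesterol synthesis (0.04) and nuclear non-coding RNAs (-0.11) turned. The TGF-beta median turned without empty vector replicate 1 (0.07) and without pre-miR-203a replicate 2 (0.04). Of the members with the smallest p, the ribosomal protein transcripts RPL12 and RPL29 had log2 changes of 2.17 ± 0.46 and 1.16 ± 0.35 (SE), and SREBF2 and STARD4 of the sterol pathway 1.60 ± 0.48 and -0.71 ± 0.32. PPM1D and FBXW7 (p53) were at 1.37 and -0.61, NFKB2 and CSF3 (inflammation) at 1.12 and -0.75, IRS1 and SOS1 (RAS and PI3K) at 0.73 and 0.83, and CDC42 and SRC (cytoskeleton) at -0.58 and 1.05. PHGDH and PSAT1, serine synthesis enzymes of the unfolded protein response list, were at -0.90 and -0.80, the hypoxia genes NDRG1 and BNIP3L at 1.04 and 0.70, and the non-coding OIP5-AS1 and MALAT1 at -0.52 and 0.52, and none of these members passed in limma. Mitochondrial MT-RNR2 and MT-ATP8 were at 0.55 ± 0.60 and 0.85 ± 1.07 (SE). Without pre-miR-203a replicate 1 MT-ATP8 passed (2.37, limma adjusted p = 0.0319), and it turned negative without empty vector replicate 1 (-0.04) and without pre-miR-203a replicate 2 (-0.67). MALAT1 turned negative without empty vector replicate 2 (-0.19).

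Mitochondrial reads made up 2% and 7.48% of the empty vector libraries and 2.31% and 12.6% of the pre-miR-203a libraries, so they differed more within each group than between the groups.

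Few markers of other cell types were tested. Of the fibroblast list 3 of 12 genes were tested and 0 passed, with COL1A1 at 2.04 ± 0.929 FPKM with the empty vector and 3.39 ± 0.782 with pre-miR-203a, and FAP at 4.44 ± 1.9 and 6.92 ± 1.48 (SD, n = 2). Of the leukocyte list CSF1R and CD14 were tested, 0 passed over all features, and both were higher adjusted over the list alone. CSF1R passed the filter only through the pre-miR-203a libraries, and without a filter 2 of 5 leukocyte markers were higher in both and 2 lower (limma's camera, adjusted p = 0.171). limma's fry passed this list upward without a filter (adjusted p = 0.0255). CSF1R stood at 0.907 ± 0.0684 and 3.52 ± 0.203 FPKM, and CD14 at 4.95 ± 0.332 and 11.7 ± 4.64 FPKM (SD, n = 2). Of the endothelial and adipocyte list 0 genes were tested.

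The authors' deposited table of the same comparison called 401 features at an adjusted p under 0.05, with 274 higher and 127 lower in the pre-miR-203a libraries. Of the 8 features that rose in limma, 7 were also called higher in the authors' deposited table, all but MIR103A2. The largest upward log2 changes of called protein-coding genes in the authors' deposited table were those of SULT1E1 at 5.33, C5AR2 at 5.07 and ATP5MD at 4.49. The authors' deposited table gave MIR203A a log2 change of 11.33, MIRLET7BHG 5.28 and MIR22HG 3.64. Downward, the authors' deposited table called ZNF367 at -2.31, GINS2 at -2.22, CDC45 at -2.05, CCNE1 at -2.27 and PLK1 at -1.84, with 14 members of the G1/S list and 8 of the G2/M list. The authors' deposited table called 10 members of the microRNA host list, 6 of the keratinocyte differentiation list, 4 of the luminal list and 2 of the reported miR-203 targets higher, and 1 of the reported targets lower.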

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

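The settings with voom and those without mitochondrial features were chosen only after the data were seen. MIR203A was higher and past the threshold in all 13 refits (log2 change 10.71 to 11.48). The microRNA host, luminal, epithelial junction, keratinocyte differentiation, G1/S, G2/M and histone lists passed camera with their direction in all 13, though without a filter the median fell from 1.04 to 0.25 for histones, from 1.06 to 0.34 for keratinocyte differentiation and from 0.89 to 0.39 for luminal genes. With an estimated correlation, 0 lists passed in any of the 13. The counts of transcripts depended on the setting. Against 8 higher and 0 lower features, the fit gave 1 and 0 without a filter, 1 and 0 on TPM, 11 and 1 with voom on recovered reads, and 21 and 0 without mitochondrial features. Leaving out 1 library gave 44 to 478 higher and 9 to 531 lower features, and the lone library of a group was then assumed to vary like the others. Each of these 4 fits included the 8 features. With pseudocounts of 0.1 and 1 the fit gave 11 and 6 higher features.

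With the replicate block, 465 features were higher and 1009 lower, and voom with the replicate block gave 1139 and 1200. The labels give only a shared number, which does not establish pairs. Deviations of same-numbered libraries from their group means correlated at 0.67 across features (0.66 without mitochondrial features), and a block on 4 libraries leaves 1 residual degree of freedom. The mitochondrial list passed camera with the block (adjusted p = 0.0179) and with voom and the block (0.0083), and not with an estimated correlation (0.663 and 0.628).

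Lists past camera went from 10 to 0 with an estimated correlation and to 3 with fry, and lay between 9 and 11 with a library left out. With fry, 0 lists passed with the replicate block, with any library left out, on TPM and with voom, 1 with voom and the block, 2 without mitochondrial features and 5 without a filter. The reported miR-203 targets had a median of -0.24 to 0.41 with a library left out, passing upward at 0.19 and 0.41, and -0.01 on TPM. AGO2 lay between -0.38 and 0.52 with a library left out and at -0.02 on TPM. Among 62 other named transcripts, 635 of 804 values stayed on the same side of the threshold with the same sign, 146 newly passed, 18 no longer passed, and 5 turned sign, all with a library left out: MT-ATP8 (-0.04, -0.67; range -0.67 to 2.37), SOCS3 (0.17, 0.31; range -0.58 to 0.31) and MALAT1 (-0.19; range -0.19 to 1.22). The cause was not tested. Alternatives that need deposited counts, and the seed match test, were not run.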

Other observations

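The test of the replicate numbers and the host test without a filter were chosen only after the results were seen, and the classes of features in the next paragraph were also drawn up then.

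Of 29 tested microRNA hairpins 15 were higher in both pre-miR-203a libraries and 1 was lower in both, with 4 past limma's threshold, and the median log2 change was 0.97 (0.66 with hairpins at 0 reads in both empty vector libraries set at their lower bound). Without MIR203A and MIR203B the median over 27 hairpins was 0.52, with 13 higher in both. The filter fixed the order of 11 of the 15, which were under 1 FPKM in both empty vector libraries, and of the 1 lower. Among the 17 hairpins whose order it left free, the median was 0.11 and 4 were higher in both, MIR203A among them. Without a filter, 16 of 30 hairpins other than MIR203A and MIR203B were higher in both and 1 was lower, with a median of 1.00, and the deposited tables themselves leave out the lowest features. MIR205 went from 3.72 and 1.48 to 72.39 and 30.61 FPKM and MIR221 from 3.38 and 0.37 to 92.22 and 32.52 FPKM, named after their values were seen (limma adjusted p = 0.0967 and 0.106). Of 15 host transcripts named after a microRNA, 12 were higher in both, 7 of them by the filter, with a median of 1.71 (0.70 over all 27 listed without a filter), while 405 other long non-coding RNAs had a median of 0.06. Of repeat families, 42 of 51 SINE, 38 of 43 LTR and 28 of 29 L1 families were lower in both pre-miR-203a libraries (medians -1.11, -0.95 and -0.88), an order that the filter fixed for 0, 8 and 5 of them, with 0 past limma's threshold and 27, 29 and 23 at an unadjusted p under 0.05. limma's camera gave p = 5.16e-18, 1.08e-17 and 5.35e-15 for these families, and p = 0.184, 0.188 and 0.163 with an estimated correlation. Repeats made up 0.268% and 0.248% of reads with the empty vector and 0.156% and 0.0942% with pre-miR-203a.

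The authors' deposited table called 5 nuclear-encoded transcripts of the respiratory chain and ATP synthase higher, ATP5MD, COX7C, ATP5MC3, ATP5PF and NDUFB4. As a class they were not higher: the 72 tested NDUF, UQCR, COX and ATP5 genes had a median log2 change of -0.16, inside the range of matched random lists (-0.23 to 0.02).

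Of all 27 listed host transcripts named after a microRNA, 17 were higher in both pre-miR-203a libraries, 1 was lower and 9 overlapped. In the fixed list, which also holds MIR203A and MIR203B, 14 of 15 were higher. A general rise of long non-coding RNA is argued against as the whole cause. The 11 hosts other than MIR203A and MIR203B had a median of 1.82. Matched random lists of other long non-coding RNAs lay between -0.27 and 0.33. The filter fixed the order of 7 of these 11 hosts. Without a filter the median was 1.71 over 13 hosts, against -0.17 to 0.28. Random lists draw genes as if independent, so these ranges do not measure the spread between libraries. The 405 other long non-coding RNAs had a median of 0.06, with 83 higher in both and 50 lower. That class also passed limma's camera upward (p = 0.00471, and p = 0.157 with an estimated correlation). For less cleavage by the Microprocessor while a precursor is overexpressed, DGCR8, whose own mRNA it cleaves, had a log2 change of 0.92 ± 0.47 (SE), at 4.42 and 7.55 FPKM with the empty vector and 7.39 and 17.44 with pre-miR-203a, and these overlapping values leave it open. More transcription of the host genes, or more of these RNAs with AGO2, also stays open without input RNA.

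The transcripts of replication and mitosis were lower in the pre-miR-203a libraries. A trend with transcript length or mean expression is argued against as the whole cause: with both trends removed, the median of the 63 genes went from -1.25 to -1.12. Matched random lists lay between -0.12 and 0.14. They draw genes as if independent, so their range does not measure the spread between libraries. It is too narrow for correlated genes, and the estimated correlation was 0.15 within the G1/S list and 0.26 within the G2/M list. A lower level of these mRNAs in cells with miR-203a, as in slower proliferation, may account for the lower values. That was not tested, since it needs input RNA.

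Among transcripts that the authors' deposited table called higher, 175 of 217 had a larger change in the replicate 1 libraries than in the replicate 2 libraries, where setting same-numbered libraries against each other is a choice that the labels do not establish. The ratio of medians, replicate 2 over 1, was 0.60 (95% bootstrap interval over genes 0.54 to 0.64). Such intervals resample genes as if independent, while each ratio rests on 1 library per group and replicate number. They do not measure the spread between replicates. The 217 transcripts were also picked by a test on these same libraries. A larger share of unspecific RNA in replicate 2 was expected to shrink every change alike. The cell cycle lists had a ratio of 1.30 (1.12 to 1.49). The explanation stays open, since unspecific RNA would also carry a change of mRNA level in the cells. Input RNA was not analysed. The ratio also depends on which empty vector library is used. Against the mean of the empty vector libraries, the G1/S median was -1.65 in pre-miR-203a replicate 1 and -1.20 in replicate 2. The G2/M median was -1.14 and -1.33. Transcripts called lower in the authors' deposited table had a ratio of 1.06 (1.00 to 1.11), and the microRNA hosts 0.87 (0.70 to 1.07). No biological explanation of the difference between replicates was tested.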
